A study of Homo sapiens with 16 samples.

How the data were processed

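RNA levels were measured by sequencing of stranded libraries from pooled human oocytes and preimplantation embryos. Per the labels, oocytes were freed of cumulus cells and frozen, embryos were thawed and pooled by stage, and blastocysts were separated by laser into an inner cell mass part, which included polar trophectoderm, and mural trophectoderm. Total RNA went into 2 library preparations per stage with the TotalScript kit, random hexamers and 5 ng of RNA per reaction. Each preparation was amplified for 12 and for 14 PCR cycles, and the authors merged the reads of both. The 2 libraries of a group therefore come from one RNA pool, so the spread between them, and every p-value given here, measures library preparation only and not the variation between pools, embryos or donors.

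The submitters' processing notes name Novoalign 2.8, DESeq2 and the human genome build hg19. The read counter, the gene annotation release, the handling of reads that map to several places and the treatment of duplicate reads are not given in the sources used here. The deposited counts are whole numbers per gene and library, with no normalization, for 19534 genes. The deposited FPKM values equal the count divided by the gene model's length and by 1 constant per library, and were used here only to check that constant against the sum of counts. Between 0.035% and 0.209% of each library's constant lay outside the table. The authors' log2 ratios give the first named group over the second, and whether they were shrunken is not stated. The authors' score for each ratio is an adjusted p-value as -10 times its log10. Gene length in bases came from the deposited table. A second deposited sheet lists 39187 gene IDs set aside for fewer than 10 counts, and none of them occurred in the main table. In 22 genes the deposited symbol had been turned into a date, and these genes were named from their gene IDs. All columns of per-sample values were matched to a sample, and 0 were left unused. Positions are those of the deposited table on hg19.

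Total counts per library ran from 5084424 to 24462198. Levels were scaled to CPM, and one count corresponded to between 0.0409 and 0.197 CPM of the library total. A library with no count of a gene still allows up to 3 counts, or 0.147 to 0.421 CPM after scaling. Reads carried no molecular identifiers, so this floor covers counting error only.

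Counts were analysed in R 4.3.3 with edgeR 4.0.16. All 16 libraries entered 1 model with a mean for each of the 8 groups, with TMM scaling, the filterByExpr filter by group and the quasi-likelihood F-test (two-sided). The filter removed 1625 genes and left 17909. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold. Levels are CPM of the scaled library size, as means ± SD of 2 libraries. Changes are log2 fold changes from the model with their SE. The common coefficient of variation was 0.114. The 9 comparisons followed the order of the stages, and those that share a group share its libraries. A gene highest in a group was called higher there than in each of the other 7 groups.

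Gene lists, 23 in all, were written from general knowledge before the data were examined, as were the comparisons and the other settings listed below unless said otherwise. They cover DUX4 target genes, PRD-like homeobox genes, oocyte growth and zona pellucida genes, the subcortical maternal complex with maternal NLRP genes, mRNA deadenylation and decay, meiosis and M-phase, DNA replication, pluripotency, trophectoderm and trophoblast, hypoblast, epithelial junctions with fluid transport, cytosolic ribosomal proteins, ribosome biogenesis, nuclear oxidative phosphorylation, mitochondrially encoded proteins, DNA methylation, replication-dependent histones, cholesterol synthesis, glycolysis, heat shock with immediate early genes, and markers of cumulus and granulosa cells, of sperm and of blood and skin cells. Each list with at least 3 tested members was tested with camera (limma 3.58.1), with the correlation between its genes estimated, and adjusted over all lists and comparisons. A preset correlation of 0.01 was an alternative. Overlaps with genes highest in CL were tested with Fisher's exact test (two-sided, 95% intervals, adjusted over the lists). The DUX4 list holds genes known from cleavage-stage embryos, so it was not blind to the stage.

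Named genes were chosen by a rule fixed before the data were examined. It takes the 8 largest rises and 8 largest falls per comparison among called genes with at least 20 CPM in the higher group and no overlap of the libraries, up to 4 called members of a list with the largest changes (or the member with the highest mean level where none was called), 22 fixed genes, and the 15 genes that stood out most in CL. Clone-based, LINC, antisense and pseudogene names were excluded. The text gives a part of the genes this rule takes.

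On simulated counts with the fitted spread, where 200 genes were changed 3-fold or 6-fold, the same steps recovered 96% to 100% of the 3-fold changes and 100% of the 6-fold changes. They called between 3 and 9 unchanged genes. The changed genes were drawn from those with at least 5 CPM and rose and fell in equal number. The simulation thus did not test scaling where many genes changed, as in CL against PN (40.1% called) and MOR against CL (50.1%). It also did not test recovery of genes under 5 CPM. Alternatives were RLE scaling, library totals alone, DESeq2 1.42.0, no low-count filter, at least 10 CPM in 2 libraries, a log2 minimum of 2, no fold minimum, the 4 compared libraries alone, the replicate number as a block, scaling without mitochondrially encoded genes, and each library left out in turn. Each fit without a library redid the filter and the scaling, so both changed along with the library. After the data had been seen, leaving out PN replicate 1 together with TROPH replicate 2 was added. Leaving out the genes of the second sheet would change nothing, since none is in the table, and it was not run. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Reads of repeats and retrotransposons were not analysed here.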

Results

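Transcripts were measured in 16 libraries from human oocytes and preimplantation embryos, in 8 groups of 2 libraries. Oocytes were immature with a germinal vesicle (GV), immature without germinal vesicle or polar body (MI), or mature (MII). Embryos were 1-cell embryos with pronuclei (PN), a pool of 2-cell, 4-cell and 8-cell cleavage embryos (CL), compacted morulae (MOR), and 2 parts of the blastocyst, the inner cell mass with polar trophectoderm (ICM) and mural trophectoderm (TROPH). Total counts were 14547851 to 22967510 per oocyte library, 13423671 to 24462198 in PN and CL, and 5084424 to 7990343 in MOR, ICM and TROPH. Across the genes tested, log2 levels of the 2 libraries of a group correlated with an r between 0.965 and 0.993, over genes that are not independent replicates. Levels are means ± SD of 2 libraries in CPM, and each adjusted p is from edgeR unless a list is named. Where a list is described, its count of called members adjusted over the list alone was the same unless both are given.

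**Figure D1:**
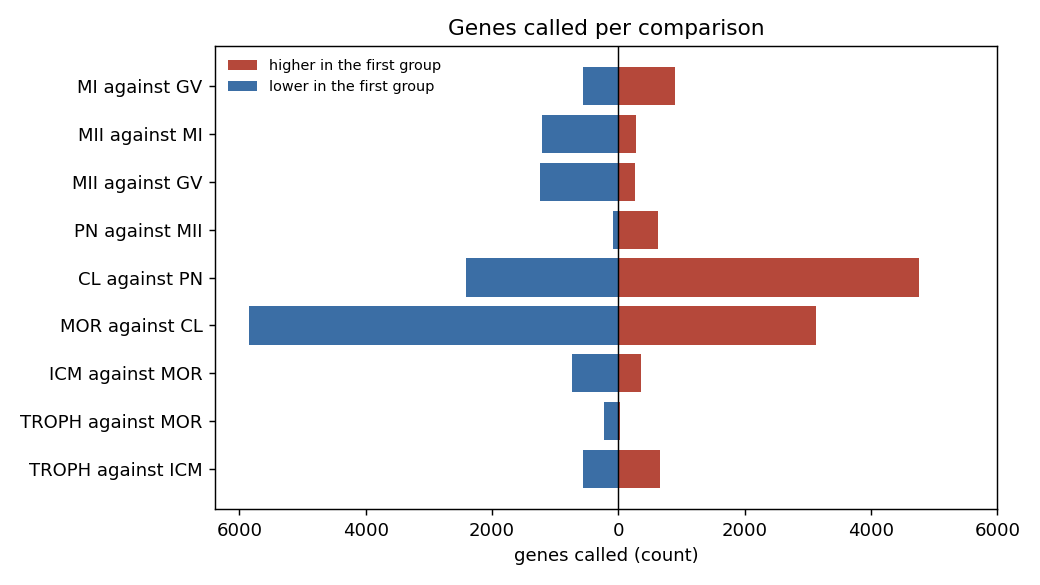
Genes called in each of the 9 comparisons, on an axis of gene counts, with genes higher in the first-named group to the right of 0 and genes lower there to the left. The bars for CL against PN (4757 higher, 2418 lower) and MOR against CL (3121 higher, 5852 lower) are the longest.

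The first step of oocyte maturation was read from MI against GV. GJA1, the gap junction protein connexin 43 (ENSG00000152661, chromosome 6, 121756837 to 121770873), stood at 318 ± 25.6 CPM in MI and 30.7 ± 1.68 in GV (log2 fold change 3.37, SE 0.10, adjusted p = 6.32e-13). The fibrillar collagens COL3A1 (log2 3.95, adjusted p = 3.93e-07) and COL1A2 (3.24, 7.98e-07), the cadherin FAT4 (4.47, 1.56e-07) and the nuclear long noncoding RNA NEAT1 (3.84, 1.8e-12) rose with it. Among falls, ATAD3C went from 245 ± 47.3 to 62.1 ± 1.29 CPM and RN7SK, the small nuclear RNA that holds the elongation factor P-TEFb, from 348 ± 65.9 to 110 ± 1.16. Of 16 tested markers of cumulus and granulosa cells, the somatic cells that surround the oocyte, 12 rose and none fell (13 adjusted over the list alone). Their median log2 fold change was 2.25 (adjusted p = 0.000191), and GJA1, COL3A1, GREM1 (2.85) and PTX3 (3.97) were among them. Remnants of somatic cells may have been in the MI pool (see Other observations), so changes in this comparison need not be the oocyte's own. Hypoblast genes, several of which encode proteins of the basement membrane, rose in 5 of 16 (6 adjusted over the list alone, median 0.89, or 0.61 with members at 0 counts in a group set to their floor, adjusted p = 0.00827), among them GATA6 (3.18), PDGFRA (2.55) and COL4A1 (3.43). The hypoblast list moved the same way as the cumulus list, and whether somatic cells carried both was not tested. DPPA5, a pluripotency gene, rose from 17.1 ± 4.45 to 88.8 ± 29.4 CPM. DPPA3 (0.655) and DNMT1 (0.905), the maintenance methyltransferase, stayed under the 2-fold minimum, while ZAR1, which binds maternal mRNA, fell by 1.09 on the log2 scale. In all, 902 genes were higher and 562 lower in MI. These counts were 599 and 433 without GV replicate 1 and 557 and 309 without GV replicate 2, the ZAR1 change was -0.94 without GV replicate 2, where DNMT1 passed at 1.16, and PTX3 stood at 2.89 without MI replicate 1 and 4.61 without MI replicate 2.

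The second step was read from MII against MI. THBS1, the matrix protein thrombospondin 1 (ENSG00000137801, chromosome 15, 39873279 to 39891667), went from 1483 ± 75.5 CPM in MI to 17.3 ± 1.71 in MII (log2 -6.43, SE 0.26, adjusted p = 3.9e-12). FAT4 (-7.04), COL3A1 (-6.42), the thrombin receptor F2R (-5.99), the collagen chaperone SERPINH1 (-5.97) and GJA1 (-5.71) fell as well. Of the cumulus and granulosa markers 14 of 16 fell (median -4.01, adjusted p = 0.00012), GJA1 and COL3A1 among them. Somatic cells in the MI pool and a change in the oocyte itself cannot be told apart here. Hypoblast genes fell in 6 of 16 (median -0.86, -0.04 with members at their floor, adjusted p = 0.0152), among them PDGFRA (-5.32) and COL4A2 (-4.20). Of the 26 heat shock and immediate early genes 5 fell, including ATF3 (-5.10) and GADD45B (-4.88), and the list as a whole did not pass (adjusted p = 0.343 with an estimated correlation). Genes of nuclear-encoded respiratory chain subunits were lower. Of 72 such genes 27 fell and none rose (33 adjusted over the list alone, median -1.02, adjusted p = 0.023), with ATP5E at -4.09 and NDUFV2 at -2.44. Of 77 cytosolic ribosomal protein genes 10 fell (13 adjusted over the list alone), RPL34 among them (-2.05), with adjusted p = 0.317 with an estimated correlation. Rises were fewer. CTRB1 (chymotrypsinogen B, 20.3 ± 0.42 CPM in MII), the zinc finger gene GLIS2 (3.44), CNNM1 (2.39), the linker histone HIST1H1E (1.36) and the helicase component CDC45 (1.03) were higher in MII. DNA replication genes passed as a list (median 0.15, adjusted p = 0.0336) with CDC45 as the 1 called member, and their median was -0.02 with library totals as the scaling. That list was at adjusted p = 0.077 and 0.0759 without MI replicates 1 and 2, 0.389 and 0.383 without MII replicates 1 and 2, 0.0547 with the replicate number as a block, 0.0759 with RLE, 0.285 with totals and 0.0624 with PN replicate 1 and TROPH replicate 2 both left out, and CDC45 was under 2-fold with library totals (0.87). In all, 286 genes were higher and 1204 lower, with 147 and 733 without MII replicate 1. The oxidative phosphorylation list was at adjusted p = 0.0582 without MII replicate 1 and 0.0605 without MII replicate 2, and the hypoblast list at 0.0582 and 0.0511, and at 0.0628 with PN replicate 1 and TROPH replicate 2 both left out. GDF9, a growth factor of the oocyte, and ZAR1 lay close to the 2-fold minimum (-1.03 and -1.04), and both were under it with RLE scaling (-0.93 and -0.94) and without MI replicate 2 (-0.97 for each), as was ZAR1 without MII replicate 1 (-0.91). CTRB1 moved from 5.02 to 4.38 without MI replicate 1 and 6.48 without MI replicate 2, GLIS2 from 3.44 to 4.11 without MI replicate 1, NDUFV2 from -2.44 to -1.62 without MI replicate 2 and ATP5E from -4.09 to -5.49 without MII replicate 1. Library totals as the scaling moved the median of all genes from -0.03 to -0.20.

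Across the whole of maturation, MII against GV, the respiratory chain genes gave the most falls of the 23 lists by number of genes. Of 72 nuclear oxidative phosphorylation genes 37 were lower in MII and none higher (41 adjusted over the list alone, median -1.32, adjusted p = 0.00827). NDUFA1, a subunit of complex I (ENSG00000125356, chromosome X, 119005449 to 119010625), went from 79.6 ± 6.11 to 12.2 ± 2.49 CPM (log2 -2.73, SE 0.15, adjusted p = 1.49e-09), and NDUFV2 from 7.57 ± 1.14 to 1.19 ± 0.23. The glycolytic enzymes TPI1 (-1.64) and GAPDH (-1.02) were among 4 of 19 glycolysis genes that fell (adjusted p = 0.504 with an estimated correlation). DPPA3, which protects the maternal genome from demethylation, rose from 1420 ± 48.0 to 3343 ± 277 CPM (1.24), while ZAR1 (-2.13), GDF9 (-1.04), the zona pellucida gene ZP2 (-1.01) and the oocyte transcription factor FIGLA (-2.31) fell. Of 21 oocyte growth and zona genes, 5 fell and none rose (3 rose adjusted over the list alone, adjusted p = 0.726 with an estimated correlation). NLRP5, a member of the subcortical maternal complex, was at 1885 ± 49.6 CPM in MII and 3866 ± 133 in GV (-1.04, adjusted p = 0.0311), a call that ended without any 1 of the 4 libraries (adjusted p from 0.0874 to 0.129). MED30 of the Mediator complex (2.92), the signal peptidase subunit SPCS2 (2.23), SAP30 (1.72), IL4 (2.11) and the cyclin CCNE1 (1.03) rose. Histone genes rose in 5 of 35 (adjusted p = 0.581 with an estimated correlation). DNA replication genes passed as a list (median 0.17, adjusted p = 0.023) with CCNE1 higher and GINS2 lower (-1.14), and was at adjusted p = 0.389 and 0.383 without MII replicates 1 and 2, 0.0722 with RLE and 0.191 with library totals. Markers of cumulus and granulosa cells fell in 9 of 16 (median -2.16, -2.01 with members at their floor, adjusted p = 0.00394), led by VCAN (-2.88), and THBS1 (-3.74) and HTRA1 (-3.65) fell with them. In all, 262 genes were higher and 1237 lower, with 102 higher without MII replicate 1. Scaling by library totals gave 161 higher and moved the median of all genes from -0.01 to -0.17. The changes of GDF9, ZP2 and GAPDH were -0.91, -0.79 and -0.85 without GV replicate 2, that of GINS2 -0.98, and that of CCNE1 0.94 and 0.98 without MII replicates 1 and 2, all under the 2-fold minimum. The replicate block placed ZP2 (-0.998) under it. RLE scaling placed GDF9 (-0.99), ZP2 (-0.96), GAPDH (-0.97) and NLRP5 (-0.99) under it, and library totals CCNE1 (0.88). The MII comparisons share the MII libraries and are not independent of each other.

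PN against MII compared the 1-cell embryo with the mature oocyte. Most transcripts stayed close to their levels in MII, with 630 genes higher and 87 lower. NLRP5 stood at 2049 ± 87.8 CPM in PN and 1885 ± 49.6 in MII (log2 0.12, adjusted p = 0.913). GJA1 went from 6.06 ± 0.17 to 120 ± 8.57 CPM (4.31, SE 0.12, adjusted p = 1.26e-13), and RGS4, a regulator of G protein signalling (4.80), SERPINH1 (4.79), CD276 (4.61) and the potassium channel gene KCNK3 (4.36) rose as well. Somatic follicle cell markers (cumulus and granulosa) rose in 8 of 16 (11 adjusted over the list alone, median 2.84, 2.37 with members at their floor, adjusted p = 0.000162), among them GJA1 and INHA, a subunit of inhibin (4.26). The cause of this rise was not tested. Hypoblast genes rose in 7 of 16, with 1 lower when adjusted over the list alone (median 1.95, 0.98 with members at their floor, adjusted p = 0.0132), GATA6 (3.79) and APOE (3.13) among them. Ribosomal protein genes rose in 8 of 77 (9 adjusted over the list alone, adjusted p = 0.136 with an estimated correlation), and 3 of 19 glycolysis genes rose (4 adjusted over the list alone, adjusted p = 0.0661 with an estimated correlation, and 0.0432 without PN replicate 2), HK1 (2.47) and PGAM1 (3.15) among them. NBPF10 (-2.41), the collagen receptor DDR2 (-2.17), the alpha tubulin TUBA1B (-1.90) and SALL3 (-1.58) fell. MOS, the kinase that keeps the mature oocyte in arrest, was at 1.40 ± 0.30 CPM in PN and 3.70 ± 0.24 in MII (-1.38, adjusted p = 0.0179), a call that ended without any 1 of the 4 libraries (adjusted p from 0.0764 to 0.164).

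Several genes of the cleavage stages were called in PN through 1 library. ZSCAN4, a DUX4 target, had 568 counts in PN replicate 1 and 30 in replicate 2, KLF17 had 610 and 4, and LEUTX 161 and 1. Of 30 DUX4 target genes 13 were called higher in PN than in MII (16 adjusted over the list alone, median 4.67, 2.29 with members at their floor, adjusted p = 0.564 with an estimated correlation). The list passed without PN replicate 2 (adjusted p = 0.0113). Without PN replicate 1 the list's median was 0.00 (adjusted p = 0.877), ZSCAN4 was at 0.36 (adjusted p = 0.982, against 0.0179 with it), and the calls of KLF17 (adjusted p = 0.765) and LEUTX (0.931) ended. They also ended without MII replicate 1 or 2, with ZSCAN4 at adjusted p = 0.0874 and 0.098, KLF17 at 0.103 and 0.0716 and LEUTX at 0.195 and 0.144. Without PN replicate 1, PRAMEF1 and ARGFX, with no count in PN replicate 2 or in MII, were at 0.00, and their calls ended without MII replicate 1 or 2 as well (PRAMEF1 at adjusted p = 0.179 and 0.126, ARGFX at 0.171 and 0.119). The replicate block ended the calls of LEUTX (adjusted p = 0.0649) and PRAMEF1 (0.0536). The sodium phosphate transporter gene SLC34A2 was called without PN replicate 1 at 3.33 in place of 8.16, and MYC at 3.97 in place of 6.04. Without PN replicate 2 they were at 9.11 and 6.82. PRD-like homeobox genes were called in 4 of 8 (adjusted p = 0.641 with an estimated correlation). Without PN replicate 1 the count of genes higher was 393, of which GATA6 was one at 2.88. The count of genes lower was 36 without MII replicate 1, 46 without MII replicate 2, 60 without PN replicate 1 and 54 without PN replicate 2. PGAM1 was at 4.32 and CD276 at 5.38 and GATA6 at 4.40 without MII replicate 1, and the hypoblast list was then at adjusted p = 0.0609, and at 0.0511 without MII replicate 2. All oocyte libraries carried one library request number and all embryo libraries another, so this comparison and the library batch cannot be told apart.

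The question of which genes turn on in the cleavage embryo was read from CL against PN, and it gave the most rises of the 9 comparisons. ZSCAN4 (ENSG00000180532, chromosome 19, 58180302 to 58190520) reached 1096 ± 64.7 CPM in CL from 15.3 ± 19.0 in PN (log2 6.12, SE 0.62, adjusted p = 1.31e-07). All 30 tested DUX4 target genes rose (median 6.12, 6.07 with members at their floor). LEUTX, a PRD-like homeobox gene (ENSG00000213921, chromosome 19, 40267234 to 40276775), reached 310 ± 6.72 CPM (6.15), the histone demethylase gene KDM4E 198 ± 6.48 (6.29), TPRX1 31.1 ± 1.05 (7.07) and DUXA 7.64 ± 1.08. As a list the DUX4 targets had adjusted p = 0.275 with an estimated correlation of 0.42 between genes, 0.0251 without PN replicate 1 and 0.0432 without PN replicate 2. Leaving out PN replicate 1 together with TROPH replicate 2, chosen after the data were seen, gave adjusted p = 0.00459. PRD-like homeobox genes rose in 7 of 8 (adjusted p = 0.447 with an estimated correlation). Pluripotency genes rose in 14 of 22 and 1 fell (median 1.92, adjusted p = 0.0428, and 0.07 with the replicate number as a block, which ended this call), with KLF17 (1271 ± 7.16 CPM, 6.30), NANOG (45.0 ± 2.55, 6.55) and SOX2 (85.4 ± 5.12, 6.23) among them, while POU5F1 stayed low at 1.09 ± 0.12 CPM (0.52, adjusted p = 0.378). Genes of the later trophectoderm rose in 10 of 33 and 1 fell (adjusted p = 0.628 with an estimated correlation), including TFAP2C (498 ± 20.5 CPM, 5.81) and GATA3 (69.0 ± 12.5, 4.94). PRAMEF22 (6.90), ZSCAN5D (6.93), MAGEA6 (6.66) and HNRNPCL4 (7.35) were among the largest rises. Reads may be shared within such families of near-identical genes, and how they were assigned is not given in the sources used here.

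Ribosome biogenesis genes rose in CL against PN in 25 of 42 and 1 fell (median 1.40, adjusted p = 0.0405, a call that 5 other settings ended), among them the RNA helicase DDX21 (1092 ± 106 CPM, 4.04), the methyltransferase fibrillarin FBL (4.35) and UTP3 (3.90). Ribosomal protein genes rose in 69 of 77 (median 1.58, adjusted p = 0.0918 with an estimated correlation), RPL34 by 3.50. Replication-dependent histone genes rose in 24 of 35 (25 adjusted over the list alone, adjusted p = 0.139 with an estimated correlation), HIST1H3C by 5.55, and 10 of 19 glycolysis genes rose and 1 fell (adjusted p = 0.0671 with an estimated correlation), lactate dehydrogenase LDHA (3.28) and PGAM1 (4.48) among them. Oocyte growth and zona genes fell in 13 of 21 (adjusted p = 0.511 with an estimated correlation, and 0.0141 with PN replicate 1 and TROPH replicate 2 both left out), among them the oocyte linker histone H1FOO (-1.98), LHX8 (-2.05) and MOS (-2.03). The subcortical complex and maternal NLRP genes fell in 7 of 14 (adjusted p = 0.489 with an estimated correlation, and 0.0247 with the same 2 libraries left out), with NLRP2 at -1.53 and NLRP5 at -1.11, and BTG4, an adaptor of maternal mRNA decay, was at -1.99. SLC39A14 (-2.52), TMEM14B (-2.52), IGFBP1 (-2.59) and RTKN2 (-2.90) were among the largest falls. In all, 4757 genes were higher and 2418 lower. The share of called genes that was higher, 66.3%, was 81.9% when libraries were scaled by totals, 54.4% with RLE scaling, 53.8% with DESeq2 and 47.3% with no low-count filter, and the median of all genes was 0.19, 0.53, -0.02 with TMM, totals and RLE. Relative to these shifts, the lists described here kept the sign of their medians under each scaling. With PN replicate 1 and TROPH replicate 2 left out 3830 genes were higher, 3733 of them shared with the 4757.

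The folds of cleavage genes over PN rested on PN replicate 1, which held more of them. Without it, ZSCAN4 was at 9.14, LEUTX at 12.04, KLF17 at 12.22, KDM4E at 11.39, NANOG at 9.25, SOX2 at 10.18, TPRX1 at 11.68, TFAP2C at 7.42, GATA3 at 6.05, MAGEA6 at 10.21, PRAMEF22 at 12.92, ZSCAN5D at 9.26, HNRNPCL4 at 11.56, FBL at 5.67 and HIST1H3C at 7.05. PN replicate 2 held 4 counts of KLF17, 1 each of LEUTX and KDM4E and none of TPRX1, PRAMEF22 and HNRNPCL4, so such values depend on the few counts left and are no bounds. Without PN replicate 2, ZSCAN4 was at 5.23, LEUTX at 5.23, KLF17 at 5.34, KDM4E at 5.39, NANOG at 5.76, SOX2 at 5.37, TPRX1 at 6.21, TFAP2C at 5.09, MAGEA6 at 5.82, PRAMEF22 at 6.01, ZSCAN5D at 6.17, HNRNPCL4 at 6.50, FBL at 3.73 and HIST1H3C at 4.90. MOS was at -2.86 without CL replicate 2. The NLRP5 change was -0.77 with library totals as the scaling. The ribosome biogenesis list was at adjusted p = 0.0568 with RLE scaling, 0.0812 without PN replicate 1, 0.0717 without PN replicate 2, 0.0547 with the replicate block and 0.064 with PN replicate 1 and TROPH replicate 2 both left out. In DESeq2 the calls of DUXA (adjusted p = 0.254) and HNRNPCL4 (0.0502) ended. The authors' deposited table gives ZSCAN4 a log2 ratio of 5.54 for CL over PN, with an adjusted p score of 94.1.

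**Figure D2:**
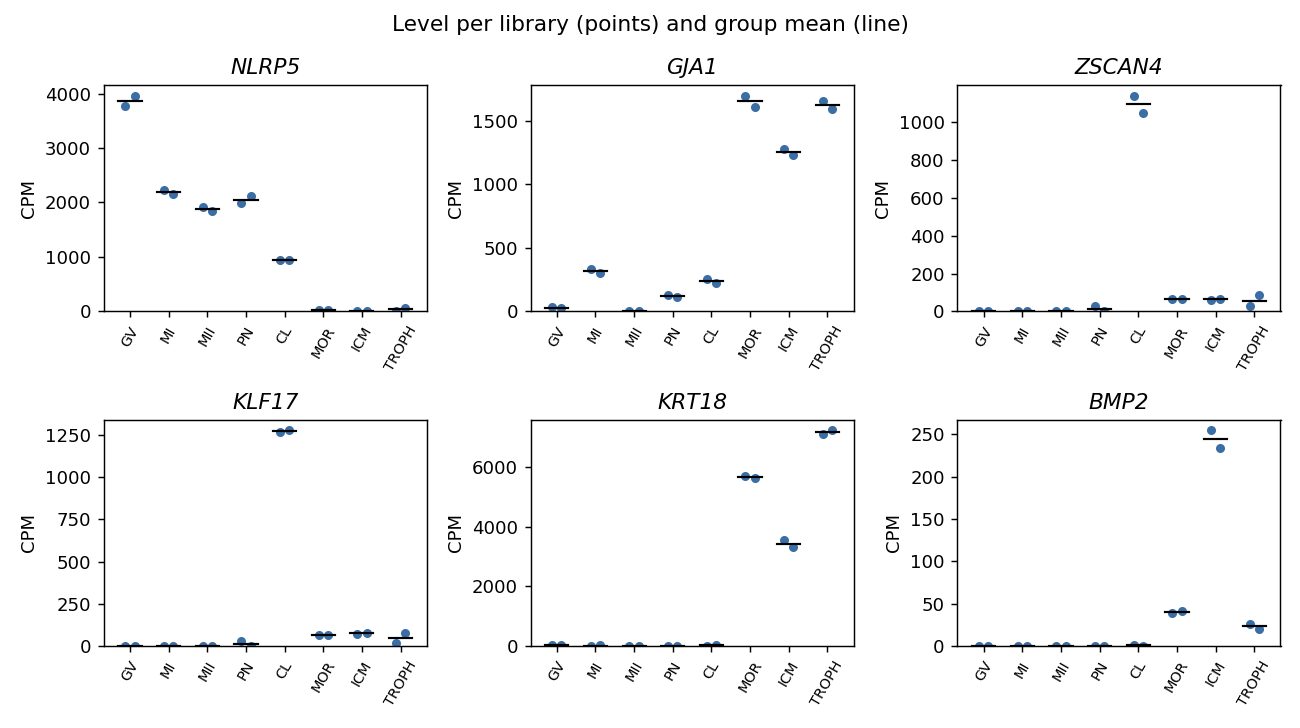
Level in CPM of 6 genes in the 8 groups, with each library as a point and the group mean as a line. The axis of each panel starts at 0, and ZSCAN4 and KLF17 stood at 1096 and 1271 CPM in CL.

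Genes that mark the cleavage embryo were taken as those higher in CL than in each of the other 7 groups. There were 802 such genes, 531 of them protein-coding, against 128 in ICM, 62 in GV, 60 in MI, 9 in MOR, 7 in PN, 4 in TROPH and 1 in MII. These counts depend on which stages were sampled, since few genes can pass in a group that resembles another. Group means correlated with an r of 0.984 for PN and MII and 0.981 for TROPH and MOR. For CL the r was 0.896 with PN and 0.819 with MOR. KCNA1, a potassium channel gene (ENSG00000111262, chromosome 12, 5019070 to 5040527), stood at 45.5 ± 0.32 CPM in CL, 48.5-fold over the nearest group. The lectin gene CLEC17A (47.1-fold), ZSCAN5C (39.7-fold), ZNF735 (37.0-fold), UBTFL1 (32.9-fold), ZNF679 (32.4-fold), PRDM8 (31.6-fold), the homeobox gene IRX5 (26.9-fold) and IRF4 (26.6-fold) followed. These folds moved with the TROPH and PN libraries, and also with the filter and scaling. Without MII replicate 1, KCNA1 was 36.5-fold over PN and IRF4 19.5-fold over ICM, the same values as with no low-count filter. Without TROPH replicate 2, ZNF735 was 65.3-fold, UBTFL1 50.3-fold, ZNF679 56.5-fold, PRDM8 65.9-fold and IRX5 41.1-fold over the nearest group. Without TROPH replicate 1, KCNA1 was 25.7-fold, CLEC17A 23.8-fold, ZSCAN5C 22.5-fold, ZNF735 20.4-fold, ZNF679 16.4-fold, PRDM8 16.8-fold, IRX5 14.5-fold and IRF4 14.4-fold. Without PN replicate 2, KCNA1 was 26.7-fold and CLEC17A 29.4-fold. With PN replicate 1 and TROPH replicate 2 both left out, a setting added after the data had been seen, KCNA1 was 127-fold, CLEC17A 231-fold, ZSCAN5C 96.8-fold, ZNF735 64.8-fold, UBTFL1 50.4-fold, ZNF679 56.1-fold, PRDM8 70.2-fold and IRX5 60.4-fold. In DESeq2 KCNA1 (44.5-fold) was not called. DUX4 target genes made up 25 of the 802, where 1.34 were expected by chance (odds ratio 110, 95% interval 41.2 to 371, Fisher's exact test, adjusted p = 3.5e-28). This test takes genes as independent, while the list did not pass in CL against PN with an estimated correlation of 0.42 (adjusted p = 0.275). That correlation is estimated from differences between replicates, and PN replicate 1 and TROPH replicate 2 held more ZSCAN4 than their partners. The outcome of the list test in CL against PN changed where these libraries were left out, as given above. The list was not blind to the stage. PRD-like homeobox genes made up 7, all but 1 of those tested (odds ratio 150, adjusted p = 3.12e-08, but 0.447 in CL against PN with an estimated correlation), and no other list passed. The PRD-like list shares LEUTX, DUXA and TPRX1 with the DUX4 list, so their results are not independent. The count of 802 was 525 to 826 without 1 library and 446 in DESeq2. The DUX4 overlap ran from 23 to 26 without 1 library and was 9 in DESeq2.

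**Figure D3:**
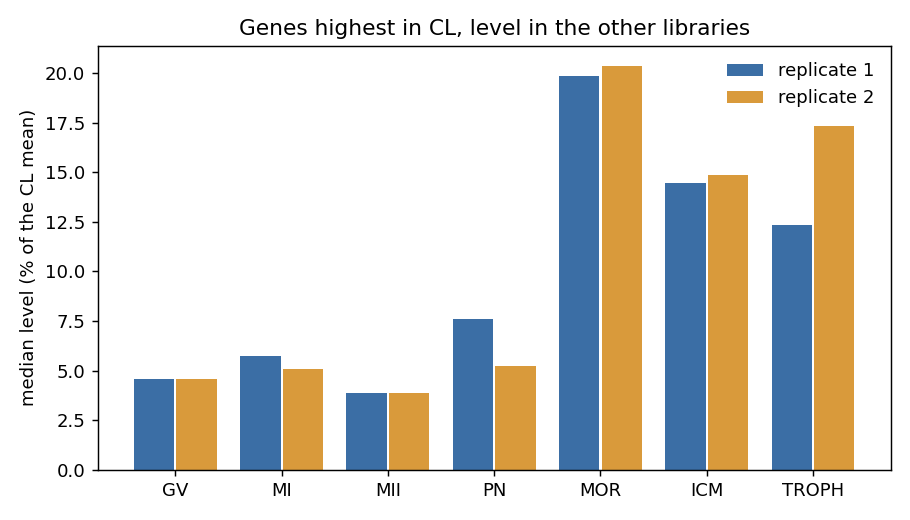
Median level of 493 genes highest in CL (with at least 5 CPM there) in each library of the other 7 groups, in percent of the CL mean, with bars for replicates 1 and 2. PN replicate 1 (7.60%) stood above PN replicate 2 (5.23%), and TROPH replicate 2 (17.4%) above TROPH replicate 1 (12.4%).

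MOR against CL compared the compacted morula with the cleavage embryo. KRT18, a keratin of simple epithelia (ENSG00000111057, chromosome 12, 53342654 to 53346620), rose from 22.2 ± 4.86 to 5663 ± 27.9 CPM (log2 8.00, SE 0.17, adjusted p = 8.7e-16). Trophectoderm genes rose in 26 of 33 and 1 fell (median 3.69, 3.09 with members at their floor, adjusted p = 0.0153), with GATA3 at 843 ± 18.6 CPM (3.61) and VGLL1 at 41.0 ± 4.68 CPM. Genes of epithelial junctions and fluid transport rose in 15 of 33 and 1 fell (median 0.86, adjusted p = 0.00151), among them the claudins CLDN4 (6.99) and CLDN10 (5.18) and the desmosome gene PKP3 (5.71). The transporter genes SLC1A3 for glutamate (9.20), SLC6A19 for neutral amino acids (8.72) and SLC12A3 for sodium chloride (8.61) rose. Pluripotency genes rose in 13 of 22 and 2 fell (median 1.46, adjusted p = 0.023), including DNMT3L (6.23), ESRRB (5.40) and POU5F1 (2.78), while NANOG stayed level (-0.43, adjusted p = 0.0951). Oxidative phosphorylation genes rose in 48 of 72 and none fell (median 1.78, adjusted p = 0.0388), NDUFS6 by 3.51. Glycolysis genes rose in 10 of 19 (adjusted p = 0.0545 with an estimated correlation), GAPDH (6942 ± 53.5 CPM, 3.52) and TPI1 (3.31) among them. Of 22 cholesterol synthesis genes 8 rose and 2 fell (adjusted p = 0.0879 with an estimated correlation), FDPS by 4.03 and MSMO1 by 3.91, and ribosomal protein genes rose in 35 of 77 (adjusted p = 0.32 with an estimated correlation).

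Genes of the cleavage and maternal lists were called lower in MOR against CL. DUX4 target genes fell in 26 of 30 (median -2.86, adjusted p = 0.782 with an estimated correlation, and 0.0274 with the 2 libraries PN replicate 1 and TROPH replicate 2 left out), and PRD-like homeobox genes in 8 of 8 (adjusted p = 0.641 with an estimated correlation). ZSCAN4 was at 67.5 ± 0.94 CPM in MOR (-4.02), LEUTX at 15.8 ± 0.08 (-4.30), KLF17 at 64.8 ± 1.97 (-4.29) and DUXA at 0.23 ± 0.33. UBTFL1 went from 34.8 ± 1.94 CPM to 0.06 ± 0.08 and CLEC17A from 29.0 ± 0.95 to 0.11 ± 0.004. All 21 oocyte growth and zona genes fell (median -4.27, -4.09 with members at their floor, adjusted p = 0.286 with an estimated correlation, and 0.0125 with the same 2 libraries left out). WEE2, an oocyte kinase that holds back meiosis, went from 8179 ± 308 to 109 ± 5.01 CPM (-6.24), H1FOO was at -6.28, GDF9 at -4.09 and ZP2 at -3.27. The maternal NLRP list fell in 11 of 14 and rose in 1 (12 lower adjusted over the list alone, adjusted p = 0.5 with an estimated correlation, and 0.0328 with them left out), with NLRP4 at -6.55 and NLRP5 at -5.16, and DNMT1 was at -5.03. The cumulus and granulosa markers moved both ways, with 4 higher, GREM1 (3.24) among them, and 5 lower (adjusted p = 0.262), and the chemokine CXCL8 reached 39.0 ± 4.43 CPM. In all, 3121 genes were higher and 5852 lower. The median of all genes was -0.47, and -0.18 or -0.20 with totals or RLE scaling. The oxidative phosphorylation list was at adjusted p = 0.0576 without CL replicate 1, 0.0511 without MOR replicate 1, 0.0515 without MOR replicate 2 and 0.068 with the replicate block, while the cholesterol list passed without CL replicate 2 (0.0471). The DUXA call ended in DESeq2 (adjusted p = 0.443). Without CL replicate 1 DNMT3L was at 7.99 and SLC1A3 at 9.87, without CL replicate 2 DNMT3L was at 5.55 and SLC12A3 at 9.38, and without MOR replicate 2 GDF9 was at -4.92. The authors' deposited table gives CL over MOR a log2 ratio of -8.25 for KRT18 (score 3040) and 4.78 for NLRP5 (score 217).

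ICM against MOR asked what the inner part of the blastocyst gained and lost. NANOG rose from 33.5 ± 3.78 to a mean of 112 CPM (log2 1.75, SE 0.21, adjusted p = 6.07e-05), and VENTX (2.89), TDGF1, a coreceptor of NODAL (2.00), and IFITM1 (1.95) rose with it, as 4 of 5 pluripotency genes that rose of 22 tested, with 1 lower (adjusted p = 0.0545 with an estimated correlation). POU5F1 (0.53), SOX2 (-0.04) and KLF17 (0.21) did not pass. Hypoblast genes rose in 7 of 16 and none fell (median 1.04, adjusted p = 0.00106). BMP2, a secreted ligand (ENSG00000125845, chromosome 20, 6748310 to 6760927), rose from 39.9 ± 1.70 to 244 ± 14.3 CPM (2.61), the receptor gene PDGFRA from 60.4 ± 1.32 to 285 ± 16.2 (2.24), and the transcription factors GATA4 (1.53) and SOX17 (1.63) rose as well. Trophectoderm genes rose in 7 of 33 and 1 fell (8 higher adjusted over the list alone, adjusted p = 0.247 with an estimated correlation), with the gonadotropin subunit CGA (2.32) and the growth factor PGF (2.17). Outside the list CGB5, the other gonadotropin subunit (2.61), ERVV-1 (3.15), SPP1 (3.35) and MT1H (2.75) rose. Heat shock genes rose in 4 of 26 (adjusted p = 0.126 with an estimated correlation, and 0.0448 with RLE scaling), among them HSPA1B (1.25), HSPB1 (1.22) and FOSB (1.68). Junction genes were lower as a list (median -0.23, adjusted p = 0.0326), with CLDN10 (-1.57) and GRHL2, a factor of epithelial identity (-1.30), called.

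In ICM against MOR, THBS1 went from 291 ± 7.33 to 0.89 ± 0.33 CPM (-8.35, adjusted p = 4e-10), VIM, the intermediate filament of mesenchyme, from 126 ± 6.20 to 4.54 ± 2.71 (-4.81), and TIMP3 from 36.1 ± 1.67 to 1.97 (-4.19). HTRA1 stood at 55.0 ± 0.92 CPM in MOR and 0.20 ± 0.28 in ICM, GREM1 at 46.4 ± 1.59 and 0.20 ± 0.28, and CXCL8 at 39.0 ± 4.43 and no count. Cumulus and granulosa markers fell in 5 of 16, GREM1 and VIM among them, and rose in 2 (6 lower adjusted over the list alone, median -0.28, -0.09 with members at their floor, adjusted p = 0.0388). In all, 352 genes were higher and 736 lower, or 32.4% higher, against 50.1% when libraries were scaled by totals and 54.9% (625 higher, 513 lower) when only the 4 libraries were used, so the direction of this split depended on the setting. The median of all genes was -0.14 and 0.00 with totals. The counts were 230 and 482 without MOR replicate 1, 224 and 503 without MOR replicate 2, and 266 and 454 without ICM replicate 1. The cumulus list was at adjusted p = 0.0506 without MOR replicate 1, 0.0535 without ICM replicate 1, 0.0651 without ICM replicate 2, 0.0528 with the replicate block and 0.163 with PN replicate 1 and TROPH replicate 2 both left out. The junction list lost its call without any 1 of the 4 libraries (adjusted p from 0.0625 to 0.0948), with RLE (0.286), totals (0.181) or the replicate block (0.0547), and with those 2 libraries left out (0.0918), and the pluripotency list gained one with RLE (0.0247) and totals (0.0355). PGF was at adjusted p = 0.0746 without ICM replicate 1, and VIM at -5.58 without ICM replicate 2.

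TROPH against MOR gave the fewest calls, with 22 genes higher and 229 lower. GATA3 stood at 1190 ± 51.6 CPM in TROPH and 843 ± 18.6 in MOR (log2 0.50, adjusted p = 0.162). HSD17B1, an estrogen-forming enzyme (1.12), ADAMTSL4 (1.25), the chemokine receptor ACKR2 (1.07) and 3 of 26 heat shock genes (adjusted p of the list = 0.286 with an estimated correlation), HSPA1A (1.21), HSPA1B (1.09) and HSPA6 (2.56), rose. Cholesterol synthesis genes were higher as a list with no single call (3 adjusted over the list alone, median 0.51, adjusted p = 0.00287), FDFT1 at 316 ± 6.56 against 213 ± 3.15 CPM. Junction genes were slightly higher as a list, again with no single call (median 0.20, adjusted p = 0.023), as were DNA replication genes (median 0.23, adjusted p = 0.0335). NANOG (-1.17) and SOX2 (-1.18) fell, as did the hypoblast genes GATA4 (-1.46) and COL4A2 (-1.41), the 2 called of 16 (3 adjusted over the list alone, median -0.32, adjusted p = 0.0428). The genes GREM1 (-6.23, adjusted p = 1.38e-09), CXCL8 (-5.28), THBS1 (-4.89), CD44 (-4.19) and VIM (-3.50) fell here too. Of 16 cumulus and granulosa markers 4 fell, VCAN (-1.89) among them, and HSD17B1 rose (5 lower adjusted over the list alone, median -0.57, adjusted p = 0.00135). Both blastocyst parts were set against the same MOR libraries, so the 2 results are not independent. The counts were 14 and 134 without MOR replicate 1, 12 and 124 without MOR replicate 2, 180 and 136 without TROPH replicate 1, and 19 and 410 without TROPH replicate 2. TROPH replicate 2 held 790 counts of ZSCAN4 and 591 of NLRP5, and replicate 1 held 233 and 111. NLRP4 stood at 427 ± 512 CPM in TROPH (1.52, adjusted p = 0.19), NLRP5 at 38.3 ± 36.4 (0.54, 0.591) and WEE2 at 267 ± 309 (1.30, 0.238), and without TROPH replicate 2 they were at -1.20, -1.07 and -1.14 and called lower. THBS1 was then at -6.04, CXCL8 at -6.40 and VIM at -4.42. Without TROPH replicate 1 the 3 maternal genes were called higher, at 2.42, 1.29 and 2.18, and THBS1 and CXCL8 were at -4.26 and -4.66. The junction list was at adjusted p = 0.137 with RLE, 0.0983 with totals and 0.0506, 0.0625 and 0.091 without MOR replicate 1, MOR replicate 2 and TROPH replicate 1, and the hypoblast list was at 0.0873 to 0.108 without any 1 of the 4 libraries, 0.0522 with RLE, 0.076 with the replicate block and 0.108 with PN replicate 1 and TROPH replicate 2 both left out. The DNA replication list was at 0.0506, 0.0625 and 0.0723 without MOR replicate 1, MOR replicate 2 and TROPH replicate 1, 0.0952 with RLE, 0.259 with totals and 0.0588 with the block. NANOG was at adjusted p = 0.132 and 0.0526 without MOR replicates 1 and 2, SOX2 at 0.055 to 0.176 without any 1 of the 4 libraries, ACKR2 under 2-fold without MOR replicate 1 (1.00) and with totals (0.99), and ADAMTSL4 at 0.0705 without MOR replicate 2.

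The 2 parts of the blastocyst were compared in TROPH against ICM. Hypoblast genes were lower in TROPH in 8 of 16 and higher in none (median -0.96, adjusted p = 0.000433). BMP2 stood at 23.2 ± 3.88 CPM in TROPH and 244 ± 14.3 in ICM (log2 -3.40, SE 0.20, adjusted p = 4.87e-09), PDGFRA at -3.11, GATA4 at -2.98 and SOX17 at -2.01. Pluripotency genes were lower in 9 of 22 and higher in none (median -0.71, adjusted p = 0.023), with NANOG at 14.9 ± 1.91 against 112 CPM (-2.91), UTF1 (-4.12), VENTX (-3.64), SOX2 (-1.14) and POU5F1 (-1.05) among them. Cholesterol synthesis genes were higher in TROPH in 10 of 22 (median 0.99, adjusted p = 0.00287), including FDFT1 (1.24), MSMO1 (1.27), LSS (1.31) and HMGCS1 (1.41). Genes of epithelial junctions and fluid transport were higher in 5 of 33 (median 0.35, adjusted p = 0.00362), with CLDN10 at 390 ± 8.17 against 101 ± 10.7 CPM (1.95), GRHL2 (1.65) and the tight junction gene TJP3 (1.24). PGF (-4.36), CGA (-4.06) and CGB5 (-4.47, a top fall outside the list) were higher in ICM, which the labels say includes polar trophectoderm, and of 33 trophectoderm genes 4 were higher and 7 lower in TROPH (median 0.09, mean -0.43, adjusted p = 0.788 with an estimated correlation). GATA3 (0.91, adjusted p = 0.00141) stayed under 2-fold and CDX2 did not pass (1.93 ± 0.49 against 0.59 ± 0.64 CPM, adjusted p = 0.226). ANXA1 (-3.94) and SPP1 (-3.48) were lower in TROPH. Oocyte genes were called higher in TROPH, as 6 of 21 oocyte growth genes (adjusted p = 0.758 with an estimated correlation) and 4 of 14 maternal NLRP genes (6 adjusted over the list alone, adjusted p = 0.641 with an estimated correlation), with NLRP4 (3.46), WEE2 (3.21), ACCSL (3.45), OOSP2 (3.18), H1FOO (2.94), NLRP5 (2.27) and TLE6 (1.92) among them. These calls ended without TROPH replicate 2, where NLRP4 was at 0.73, WEE2 at 0.76, ACCSL at 0.99, OOSP2 at 0.24, H1FOO at 0.60, NLRP5 at 0.65 and TLE6 at -0.09. Those of OOSP2 and TLE6 also ended without ICM replicate 2 (adjusted p = 0.0535 and 0.237). Without TROPH replicate 1 both lists passed (adjusted p = 0.00354 for each). NLRP4 was then at 4.35, WEE2 at 4.08, ACCSL at 4.32, OOSP2 at 4.09, H1FOO at 3.80, NLRP5 at 3.02 and TLE6 at 2.73, and without ICM replicate 1 TLE6 was at 3.13. Cumulus and granulosa markers were higher in 3 and lower in 2 of 16 (median 0.74, 0.00 with members at their floor, with the test on the lower side, adjusted p = 0.641).

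In all, 652 genes were higher and 555 lower in TROPH than in ICM, and 347 were higher without TROPH replicate 2. With PN replicate 1 and TROPH replicate 2 left out 363 were higher, 297 of them among the 652. The share higher was 54.0%, against 44.7% with RLE, 48.3% with DESeq2, 38.1% with no low-count filter, 23.0% with only the 4 libraries, 74.7% with no fold minimum, 71.0% and 40.8% without TROPH replicates 1 and 2, and 29.0% with library totals, where the median of all genes moved from 0.14 to -0.06. The junction list was at adjusted p = 0.0568 with RLE scaling. POU5F1 was at adjusted p = 0.323 without ICM replicate 1, 0.139 without TROPH replicate 1 and 0.127 without TROPH replicate 2, and SOX2 at 0.0663 without ICM replicate 1. The HMGCS1 call ended without ICM replicate 1 (adjusted p = 0.0992), ICM replicate 2 (0.135) or TROPH replicate 2 (0.197), and that of LSS without any 1 of the 4 libraries (0.0531 to 0.153). With library totals HMGCS1 (0.0888), LSS (0.0987) and TLE6 (0.0747) were not called. FDFT1 and TJP3 were at 0.99 and 0.98 with library totals. CGB5 was at -5.41 without TROPH replicate 1 and -3.89 without TROPH replicate 2. The authors' deposited table gives BMP2 a log2 ratio of 3.48 for ICM over TROPH, with a score of 705. A preset correlation of 0.01 added 56 list calls to those with an estimated correlation.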

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

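Among the settings described here, leaving out PN replicate 1 and TROPH replicate 2 together was chosen only after the data had been seen. No result below had its cause tested unless a reason is given. Where a library is left out, its group has 1 library left, which is assumed to vary like the other groups. The filter and the scaling then change too, so a lost call does not show dependence on that library alone. Without MII replicate 1, 18803 genes were tested in place of 17909. The median of all genes then moved from -0.013 to -0.13 in MII against GV and from 0.038 to 0.232 in PN against MII.

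Without 1 library, genes higher and genes lower ranged from 557 to 918 and from 309 to 557 for MI against GV, 147 to 319 and 733 to 1141 for MII against MI, 102 to 234 and 863 to 1047 for MII against GV, 393 to 585 and 36 to 60 for PN against MII, 3786 to 4472 and 2195 to 2416 for CL against PN, 2747 to 2923 and 5016 to 5506 for MOR against CL, 224 to 266 and 454 to 560 for ICM against MOR, 12 to 180 and 124 to 410 for TROPH against MOR, and 347 to 965 and 394 to 504 for TROPH against ICM. Genes highest in CL ranged from 525 to 826 and DUX4 targets among them from 23 to 26. Counts above those with all libraries were the 180 and 965 higher in TROPH without TROPH replicate 1, 410 lower in TROPH against MOR without TROPH replicate 2, 290 and 319 higher in MII against MI without MI replicates 1 and 2, 918 higher in MI against GV without MI replicate 2, 826 highest in CL without MI replicate 1 or 2 and 26 DUX4 targets without CL replicate 2.

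With the replicate number as a block, the counts were 876 and 546, 277 and 1168, 259 and 1223, 618 and 85, 4656 and 2407, 3071 and 5781, 342 and 722, 20 and 223, and 630 and 539 in the order above, with 773 genes highest in CL and 25 DUX4 targets among them. The numbers carried no pairing across groups, since the deviations of replicates correlated between -0.042 and 0.096 over 28 pairs of groups.

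With no fold minimum, which admits smaller changes by construction, genes higher and lower were 1785 and 1968 (MI against GV), 1299 and 1902 (MII against MI), 1495 and 2203 (MII against GV), 1112 and 594 (PN against MII), 638 and 2163 (ICM against MOR) and 226 and 381 (TROPH against MOR). There were 4376 lower in CL against PN, 2457 higher in TROPH against ICM and 1236 highest in CL. A log2 minimum of 2, which admits fewer, gave 447 and 157, 108 and 713, 38 and 355, 392 and 16, 129 and 357, 3 and 110 for the same 6, with 377 lower in CL against PN, 1747 higher in MOR against CL, 250 and 257 in TROPH against ICM and 422 highest in CL.

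At least 10 CPM in 2 libraries, which tests fewer genes, gave 449 and, rounded, 2.2e2 (MI against GV), 114 and 702 (MII against MI), 139 higher (MII against GV), 2149 and 1078 (CL against PN), 1835 and 2785 (MOR against CL), 404 lower (ICM against MOR), 405 higher (TROPH against ICM) and 370 highest in CL. Library totals gave 161 higher (MII against GV), 1281 lower (CL against PN), 470 lower (ICM against MOR) and 305 higher (TROPH against ICM). No low-count filter gave 4345 lower (CL against PN) and 398 higher (TROPH against ICM). The 4 compared libraries alone gave 176 lower (PN against MII), 625 higher and 513 lower (ICM against MOR) and 198 higher (TROPH against ICM). DESeq2 gave 430 higher (MII against MI), 52 higher (TROPH against MOR), 446 highest in CL and 9 DUX4 targets among them. Leaving out PN replicate 1 and TROPH replicate 2 together gave 438 lower (TROPH against MOR) and 363 higher (TROPH against ICM). For all of these the cause was not tested.

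The direction of 4 named genes and of the tests of 2 lists reversed, and 2 genes lost all change. Without PN replicate 1, PRAMEF1 and ARGFX were at 0.00 in PN against MII, and again at 0.00 with both libraries left out, because their counts lay in that library, while without PN replicate 2 they stood at 9.29 and 9.26, values against groups with no count and no bounds. Without TROPH replicate 2, NLRP4 (-1.20), NLRP5 (-1.07) and WEE2 (-1.14) in TROPH against MOR and TLE6 (-0.086) in TROPH against ICM fell to the other side, and with both left out they were at -1.22, -1.08, -1.16 and -0.062. Without TROPH replicate 1 NLRP4, NLRP5 and WEE2 stood at 2.42, 1.29 and 2.18, and without ICM replicate 1 TLE6 stood at 3.13. In TROPH against MOR the median of the maternal NLRP list was -1.12 without TROPH replicate 2 and -1.14 with both left out, against 0.99 without TROPH replicate 1, and that of the oocyte growth list, 0.00 with all libraries and a test on the lower side, was 0.30 with a test on the higher side without TROPH replicate 1 and -1.32 without TROPH replicate 2.

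Of 291 changes of named genes, 284 kept direction and call with RLE scaling, 280 with library totals, 277 with DESeq2, 286 with no low-count filter, 287 with the block, 291 with scaling free of mitochondrially encoded genes and 269 with both libraries left out. Of 198 list tests, 187 did so with RLE, 192 with totals, 190 with the block, where 8 became weaker (adjusted p from 0.0528 to 0.076), and 142 with a preset correlation. The settings for FPKM values did not apply, since counts were used, and leaving out genes on the second sheet was void. In ICM, 3 counts correspond to 0.393 and 0.421 CPM after scaling, so absence there means less than in PN replicate 1 (0.152 CPM).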

Other observations

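The tests of library material, of depth and of somatic cells reported below were chosen only after the result was seen, and the test of gene length was fixed before.

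Single genes of several maternal and cell cycle lists moved between CL and MOR, while none of the lists given here for that step passed. Of 28 mRNA deadenylation and decay genes 14 fell and 1 rose (median -1.17, adjusted p = 0.211 with an estimated correlation), and PABPN1L, a poly(A) binding protein of the egg, went from 6.28 ± 1.26 CPM to no count. Of 33 regulators of meiosis and M-phase 14 fell and 2 rose (adjusted p = 0.296 with an estimated correlation), with the kinase gene AURKC at -3.76 and the securin gene PTTG1 at -3.91. In CL against PN the same list had 7 lower and 2 higher (adjusted p = 0.579), CCNB3 at -2.45 and WEE1 at 4.48, and its median of -0.15 was 0.19 with library totals as the scaling. DNA methylation genes moved apart, with 6 higher and 7 lower in MOR against CL (adjusted p = 0.726). The glycosylase TDG rose by 5.96 there and DNMT1 was at -5.03, while the dioxygenase TET1 had risen in CL against PN (4.44). The median of this list, -0.07, was 0.20 with RLE scaling. Linker histone HIST1H1A fell (-4.54) while the core histones HIST1H4C (5.63) and HIST1H2BM (3.31) rose, in a list with 12 higher and 9 lower (adjusted p = 0.698). Ribosome biogenesis genes had 11 lower and 1 higher (adjusted p = 0.757), with RRN3, a factor of RNA polymerase I, at -2.24. DNA replication genes had 6 higher and 9 lower (adjusted p = 0.891), PCNA at -1.65.

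Single members of other lists were called in CL against PN and in ICM against MOR, while none of the lists given here for them passed. Heat shock and immediate early genes rose in 12 of 26 and fell in 2 in CL (adjusted p = 0.296), with JUNB at 5.25. Cholesterol synthesis genes had 2 higher and 4 lower (3 higher adjusted over the list alone, adjusted p = 0.129), IDI1 at 3.52 and FDFT1 at -1.90. Junction genes had 11 higher and 2 lower (median 0.21, -0.02 with RLE scaling, mean 0.83, test on the lower side, adjusted p = 0.901). The only mitochondrially encoded protein gene in the table, MT-ND3, rose by 1.52 and was not tested as a list. Markers of other cell types were low. Of 4 tested sperm markers 2 rose in CL (adjusted p = 0.931), OAZ3 to 3.96 ± 0.10 CPM, and all 5 blood and skin markers rose (adjusted p = 0.422), LYZ to 2.61 ± 0.38 CPM and PTPRC to 2.12 ± 0.20. The globin genes HBA1 (5.49) and HBA2 (5.28) rose by more than LYZ (3.70). HBA1 was at 7.45 and 4.77 without PN replicates 1 and 2, and HBA2 at 4.29 and 7.28. Without PN replicate 1 WEE1 was at 5.21, JUNB at 6.23, IDI1 at 5.17 and LYZ at 5.16, and without PN replicate 2 IDI1 was at 2.84 and LYZ at 3.05. In ICM against MOR 6 of 21 oocyte growth genes fell (median -1.52, -1.24 with members at their floor, adjusted p = 0.698), 4 of 14 maternal NLRP genes (adjusted p = 0.752) and 2 of 30 DUX4 targets (7 adjusted over the list alone, adjusted p = 0.931), RFPL4A among them (-1.91).

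Symbol families among the 802 genes highest in CL were counted after the data had been seen, with Fisher's exact test over 6 families. PRAMEF genes, which overlap the DUX4 list, held 18 of 19 tested (odds ratio 392, adjusted p = 4.77e-23, a test that takes these near-identical genes as independent), MAGE genes 8 of 20 (odds ratio 14.3, adjusted p = 3.66e-06) and ZNF genes 38 of 451, where 20.2 were expected (odds ratio 2.01, adjusted p = 0.000372). Olfactory receptor genes (4 of 63, adjusted p = 0.55) and LINC genes (11 of 214, adjusted p = 0.739) did not pass, and no KRTAP gene was tested.

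Genes highest in CL stood higher in PN replicate 1 than in PN replicate 2, by a median of 2.28% of their CL level, and higher in TROPH replicate 2 than in TROPH replicate 1, by 4.63%, against -0.19% to 0.35% in the other 5 groups. Depth was tested by thinning the deeper library. The summed counts then differed by 1.18 and 1.21 times, inside a bound of 1.5 that was too wide to decide. A second test, added afterwards, gave 86.3% and 82.2% of the differing genes with more counts in PN replicate 1 and TROPH replicate 2. It only restated the pattern, since levels were already scaled. Other values argue against depth as the cause for the 493 genes used. MII replicate 1 was deeper than MII replicate 2 (total counts 21919656 against 14547851), yet their scaled medians were 3.86% and 3.88% of CL. Totals lay closer together in PN (24462198 and 20248797) and TROPH (7460653 and 7990343). For replicates 1 and 2 the medians there were 7.6% and 5.23% in PN, and 12.4% and 17.4% in TROPH. CL library material may be present in PN replicate 1 and TROPH replicate 2. The reason is that the median excess was nearly the same share of the CL level at low, middle and high abundance (ratio of highest to lowest 1.07 and 1.08). Single genes varied, with quartiles of 0.84% and 3.33% for PN replicate 1 and 1.88% and 7.02% for TROPH replicate 2. Of the 493 genes, 82.2% and 82.8% stood above the partner library. Equal medians alone do not show where the excess came from. A fit of group profiles, however, gave 2.52% of CL beside 2.29% of MII for PN replicate 1. For TROPH replicate 2 it gave 4% of CL beside 12.67% of MOR. Group means of MII and PN (r 0.984) and of MOR and TROPH (r 0.981) were alike, so the fit cannot separate shares of MII and MOR from the library's own stage. Both libraries of a stage came from one RNA pool, so a difference between embryos could not produce this, and no biological explanation was tested.

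Cumulus and granulosa markers were higher in MI than in MII (14 of 16), and in ICM against MOR 5 of 16 were lower and 2 higher. A second list of 36 abundant somatic genes, none in another list, had 27 tested, of which 5 reached 10 CPM in MII. Of the 27, 15 were called higher in MI than in MII and 1 lower, and in MI against GV 12 were higher and 1 lower. Remnants of somatic cells may therefore have been in the MI pool although oocytes were denuded. CYR61 stood at 208.9 CPM in MI against 13.8 in MII and COL6A1 at 56 against 3.1. S100A6 and TPM2 (0.2 CPM) and ANXA2 (1 CPM, against 0.1 in GV and MII) stayed very low in MI. In no group did S100A6 pass 4.6 CPM (TROPH) or TPM2 1.6 CPM (CL). Levels of these genes in somatic cells were not measured here, so they cannot bound the share of such cells. TPM1 (200.9 against 214.8) cannot tell, since MII itself held it at a high level. In MOR 6 of the 27 were called higher than in ICM, and somatic cells and a change in the embryo's own genes cannot be told apart there, since 11 of the 27 reached 10 CPM in ICM itself. Stage of maturation is the biological alternative for MI and stays untested, and the cause was not tested for PN, where 11 of the 27 were called higher than in MII and none lower, or for MOR against CL, with 12 higher and 2 lower. Hypoblast genes moved the same way as the cumulus markers in MI against GV, MII against MI and PN against MII. Whether the same cells carried both lists there was not tested, so these calls do not show a hypoblast programme in oocytes or 1-cell embryos.

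Nuclear oxidative phosphorylation genes fell between GV and MII, and their gene models are short (median 2062 bases against 3532 for all). Of 10000 random lists matched on gene model length and level, none had a median as low as -1.32. Their lower 2.5% bound was -0.47, so gene model length could account for at most a part of the fall. The length of the transcripts themselves was not used, so a bias by transcript size was not tested. Matched lists also lack the correlation between genes of a real list. Ribosomal protein genes had a median of -0.38, as low in 23 of 10000 matched lists, but such lists hold no correlation between genes, and the list did not pass with an estimated one (7 of 77 lower, adjusted p = 0.659). The rank correlation of change with length was 0.174 in this comparison and 0.171 in MI against GV. A shift in RNA yield between stages and the maturation of the oocyte stay open and were not tested.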
